A study of Escherichia coli with 8 samples.

How the data were processed

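Total RNA of E. coli MG1655 cells given CORM-3 (30 µM, 15 min) and of control cells was labelled with Cy3 and Cy5 and hybridised together on 2-colour arrays. There were 4 biological experiments with a dye exchange each, and the labels name the RNA behind each dye. The deposited values are log2 Cy3/Cy5 ratios, 1 column per array. According to the submitters' design text, the authors quantified spots with Imagene 4.0 with local background correction. The text also says that spots marked as bad, negative or poor were removed and that the log2 ratios were normalised with Lowess in GeneSight 3.5. The deposited table holds no intensities or marks, and nearly every probe has a value on all 8 arrays. How removed spots were filled is therefore not known, and some ratios may be filled-in values. On no array did more than 12 probes share one identical ratio, which does not exclude other ways of filling. Lowess removes a trend of the ratio with brightness within an array and centres it, so a shift shared by nearly all genes would not be seen. Spot brightness was not used here, so dim and bright spots carry the same weight. The medians of the 8 deposited columns lay between -0.074 and 0.097.

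The deposited log2 ratios had not been turned for the dye exchange. The 2 arrays of an experiment correlated at r = -0.25 to -0.079 across genes and unnamed probes, and arrays of one orientation at r = 0.25 to 0.48. Ratios of arrays with CORM-3 RNA in Cy5 were therefore turned by sign, which makes every value CORM-3 over control. The 2 arrays of an experiment were averaged, so that a fixed dye effect cancels and each experiment counts once. The design text says that the arrays of an experiment hold the same pair of RNAs, and this is the source of the pairing. As a check, deviations from the orientation means correlated at 0.024 to 0.077 between arrays of the same experiment and at -0.088 to 0.036 between arrays of different experiments.

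The table held 4608 probes, of which 4325 had a value on all 8 arrays, 4 on some and 279 on none. The platform annotation gave 1 gene symbol to 4087 probes, several to 0 and none to 521. Symbols of 197 probes were updated through gene identifiers in a table of the MG1655 annotation (assembly ASM584v2), and 1 identifier had no match there. That table was used only for names and for the order of neighbouring genes. Probes of one gene were averaged. This concerned 48 genes, and the probes of the 4 called among those with several complete probes did not differ in sign. A gene was tested when at least 3 experiments had both arrays, which left 4032 named genes and 248 unnamed probes. No probe bore the name cpxP or gadA in the annotation used, and flgA had no tested value.

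The test was limma's lmFit and eBayes (limma 3.58.1, statmod 1.5.0, R 4.3.3) on the 4 experiment means against 0, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The authors' design text asks for a change of at least 2-fold and a P value under a limit that is not complete in the text used here. The count with at least 2-fold is therefore given beside the adjusted one. On simulated data with the spread of the 4279 genes complete in all experiments, 200 of them changed, the test recovered 18% of genes changed by log2 1 and 84% of those changed by log2 2. Of its calls 5.56% were genes simulated without a change, and none had the wrong direction.

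The 31 gene lists, with 503 members of which 500 were measured, were written from textbook knowledge. They were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, with adjustment over the 31 lists. Each list's calls are counted over all genes and adjusted over the list alone. Genes to name were the 12 highest and 12 lowest ratios among changed genes with a symbol and with the same sign in all 4 experiments, the 4 members of each list with the smallest p, and a fixed set of stress, oxidase and regulator genes. This gave 142 genes. The limit to genes with a symbol was not part of the fixed rule, and it left out 3 unnamed probes that would rank among the 12 highest. Other genes were named after their values were seen, namely the remaining members of lists, the 2 unnamed probes, yeeP and pyrE, and all genes first named under other observations. The lists, the naming rule, the test and its alternatives were fixed before the data were examined.

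The alternatives were all 8 arrays as independent values, the experiment as a random block without and with a dye term, and each orientation alone. Further ones were median centring, equal spread and quantile normalisation, other rules for missing values, robust eBayes, array weights, a plain one-sample test with a 2-fold limit, and each experiment left out. Intervals are 95% bootstrap intervals from 10000 draws or exact binomial intervals. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.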

Results

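The series measured how the transcriptome of Escherichia coli responded to CORM-3, a water-soluble ruthenium carbonyl that releases carbon monoxide. Strain MG1655 was grown with air in a defined minimal medium with glycerol as the carbon source, to the middle of exponential growth. CORM-3 was then added to 30 µM, a dose chosen by the submitters because it slowed growth only slightly. RNA was taken after 15 min and compared with RNA of control cells on 2-colour arrays. There were 4 biological experiments, each hybridised on 2 arrays with the dyes exchanged, giving 8 arrays in all. Each array held 4327 probe values, with SDs of the log2 Cy3/Cy5 ratio from 0.977 to 1.33. Every ratio below is log2 of CORM-3-treated over control RNA, averaged over the 2 arrays of an experiment. Each ± value is the SD over the 4 experiments (n = 4), and the number of experiments sets the precision. Each adjusted p is limma's with Benjamini-Hochberg adjustment, or camera's for a gene list.

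Genes called higher with CORM-3 included 11 of 14 Cpx and 7 of 8 Bae envelope stress genes, and genes called lower included all 5 cytochrome bo oxidase genes and 14 of 16 citric acid cycle genes. These 4 lists passed camera at the preset correlation, and none of the 31 lists did with an estimated correlation (lowest adjusted p = 0.083). The largest rise was that of ymgD (b1171), a small uncharacterised protein, at 5.06 ± 1.23, or 33.3-fold (adjusted p = 5.7e-05). spy (b1743), a periplasmic chaperone, rose 26.0-fold (4.70 ± 1.67, adjusted p = 0.00032). The deepest falls were those of sdhC (b0721), a membrane subunit of succinate dehydrogenase, at -4.49 ± 0.79, and of cyoB (b0431), the catalytic subunit of cytochrome bo oxidase, at -4.47 ± 0.58. These were 22.5-fold and 22.1-fold lower (adjusted p = 2.6e-05 and 1.7e-05).

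Of 4280 genes and unnamed probes tested, 274 (6.40%) passed an adjusted p of 0.05, with 122 higher and 152 lower. All 274 also changed at least 2-fold, the smallest by 1.01 on the log2 scale, and 273 had the same sign in all 4 experiments. Smaller changes would mostly be missed, since the test recovered only 18% of genes simulated with a change of log2 1. The count of changed genes rested partly on the number of experiments. It was 162, 153, 151 and 214 with experiment 1, 2, 3 or 4 left out. It also differed between the dye orientations, with 276 on the 4 arrays with CORM-3 RNA in Cy3 alone (169 of them among the 274) and 102 on the 4 with it in Cy5 (92 among the 274).

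**Figure D1:**
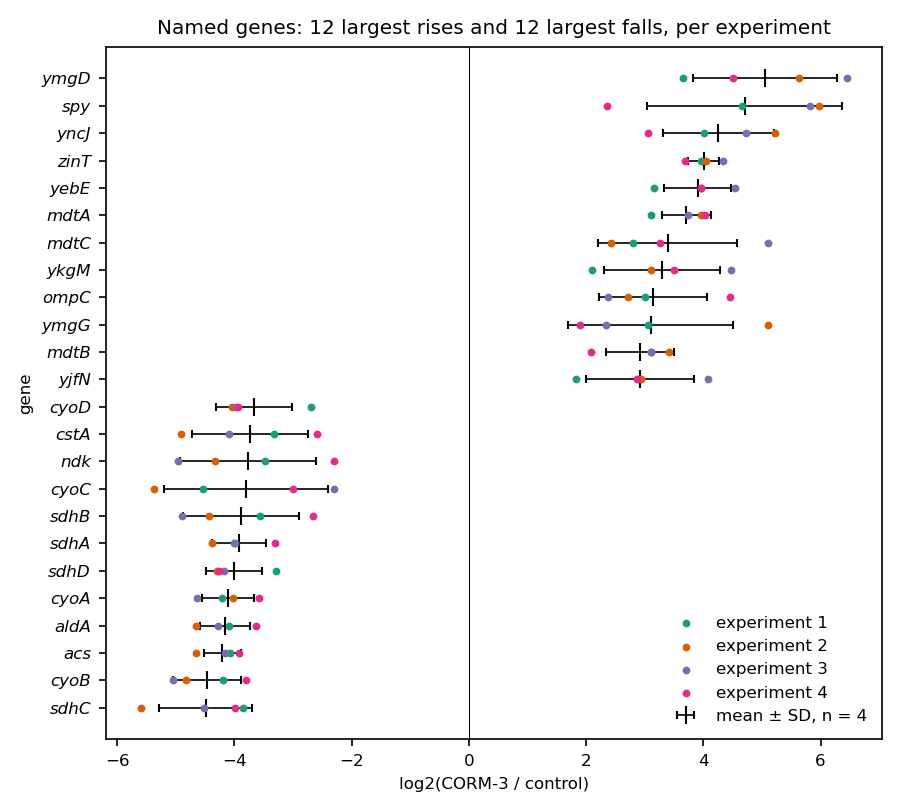
Log2 ratio of CORM-3-treated over control RNA in each of the 4 experiments (coloured points, mean of 2 dye-swapped arrays) for the 12 named genes with the largest rise and the 12 with the deepest fall among the 266 changed genes that have a name, with mean ± SD (black, n = 4). The points of ymgD lie between 3.65 and 6.45, those of zinT near 4.00 and those of sdhC between -5.60 and -3.85.

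Among the other leading rises, yncJ (b1436) reached 4.25 ± 0.95, or 19.1-fold. ompC (b2215), a general porin of the outer membrane, rose 8.78-fold (3.13 ± 0.92, adjusted p = 0.00041). ymgG (b1172) averaged 3.10 ± 1.41, but its response was 5.71 with CORM-3 RNA in Cy3 and 0.49 with it in Cy5. 3 unnamed probes stood among the leading rises as well, and the 2 highest, 3.1.13.12 and 2.1.13.12, were at 4.56 ± 0.50 and 4.52 ± 0.62 (adjusted p = 1.7e-05 for each). Leading falls outside the respiratory genes included acs (b4069), acetyl-CoA synthetase, at -4.21 ± 0.31, or 18.5-fold lower. aldA (b1415), an aldehyde dehydrogenase, was at -4.16 ± 0.42, or 17.9-fold lower. ndk, nucleoside diphosphate kinase, was at -3.77 ± 1.16, and cstA, a transporter induced by carbon starvation, at -3.73 ± 0.99 (adjusted p = 0.00026 and 0.00017).

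Envelope stress genes held many of the highest ratios. The Cpx system senses misfolded protein in the envelope, and 11 of 14 measured members of its list rose, 12 when adjusted over the list alone. yebE (b1846) rose 14.9-fold (3.90 ± 0.57, adjusted p = 3.0e-05). yjfN reached 2.92 ± 0.92, htpX, an inner membrane protease, 2.63 ± 0.41, and yccA 2.01 ± 0.43. The periplasmic protease gene degP was at 2.71 ± 1.60 and the regulator gene cpxR at 2.15 ± 0.85 (adjusted p = 0.0089 and 0.0038). degP was at 3.85 with CORM-3 RNA in Cy3 and at 1.58 with it in Cy5. cpxA was at 0.79 (adjusted p = 0.14) and ppiD at -0.30 (adjusted p = 0.67). The 14 Cpx genes had a median of 1.65, with a camera adjusted p of 1.3e-13 at the preset correlation and an adjusted p = 0.11 with an estimated correlation. Without experiment 2, 7 of its members were called.

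The Bae system controls envelope repair and drug efflux, and 7 of its 8 listed genes rose, also when adjusted over the list alone. mdtA, mdtB and mdtC, which encode a multidrug efflux pump, were at 3.71 ± 0.42, 2.93 ± 0.58 and 3.39 ± 1.19, or 13.1-fold, 7.60-fold and 10.5-fold higher. mdtC was at 4.72 with CORM-3 RNA in Cy3 and at 2.07 with it in Cy5, where its call ended. acrD, another efflux pump, was at 2.66 ± 0.62 (adjusted p = 0.00045). mdtD, the remaining member, was at 0.59 (adjusted p = 0.35). The 8 Bae genes had a median of 2.79, with a camera adjusted p of 3.2e-13 and an adjusted p = 0.093 with an estimated correlation.

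Of the 7 phage shock genes, which answer damage to the inner membrane, pspA, pspB and pspD rose, both over all genes and adjusted over the list alone. pspA was at 1.86 ± 0.48, pspD at 1.68 ± 0.80 and pspB at 1.45 ± 0.20 (adjusted p = 0.0030, 0.013 and 0.0082), while pspE was at -0.63 (adjusted p = 0.23). Over its 7 genes this list had a median of 0.35, with a camera adjusted p of 0.044 and an adjusted p = 0.20 with an estimated correlation. Without experiment 1 the calls of pspB (1.43) and pspD (1.31) ended, and the list's own call ended without experiment 2 or experiment 3. Of the 13 sigma E genes, fkpA, a periplasmic folding catalyst, was the only one called, 2.38-fold higher (adjusted p = 0.028), also over the list alone. Its call ended with any 1 experiment left out (1.02 to 1.40). rpoE was at 0.83 (adjusted p = 0.18), and the list's camera adjusted p was 0.58.

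Among the metal lists, the highest ratios were those of 3 zinc uptake genes. zinT (b1973), a periplasmic zinc-binding protein, rose 16.1-fold (4.00 ± 0.27, adjusted p = 1.7e-05). znuA and znuC, parts of the high-affinity zinc importer, were at 2.25 ± 0.87 and 1.57 ± 0.37 (adjusted p = 0.0030 and 0.0070). These were the 3 of 12 zinc genes that passed, over all genes and over the list alone. zntA, which exports zinc, was at -0.10 ± 0.45 (adjusted p = 0.89), and zur, the repressor of zinc uptake, at 0.40 (adjusted p = 0.54). The uptake genes znuB, of the same importer, and zupT were at -0.16 and -0.013 (adjusted p = 0.86 and 0.99). The 12 zinc genes had a median of 0.12, with a camera adjusted p of 0.011 and an adjusted p = 0.15 with an estimated correlation. ykgM (b0296), a ribosomal protein paralogue made under zinc shortage, rose 9.82-fold (3.30 ± 0.99, adjusted p = 0.00036).

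Of 30 iron uptake genes, 4 rose, and 6 when adjusted over the list alone. These were feoA (1.53 ± 0.88) and feoB (1.23 ± 0.47) of the ferrous iron importer, fhuA (1.24 ± 0.72), a ferrichrome receptor, and entB (1.17 ± 0.42), an enterobactin synthesis gene. Their adjusted p ran from 0.026 to 0.048. feoB rested on 1 orientation, with 2.63 when CORM-3 RNA was in Cy3 and -0.18 when it was in Cy5. The number of called iron genes was 0 without experiment 1, 2 or 4 and 1 without experiment 3. The 30 iron genes had a median of 0.31, with a camera adjusted p of 0.011 and an adjusted p = 0.15 with an estimated correlation. No gene of the 9 copper homeostasis genes or the 13 iron-sulfur cluster assembly genes was called by limma, over all genes or over the list alone. At an unadjusted p under 0.05 the copper list had 0 and the iron-sulfur list had 1 higher and 1 lower. Their camera adjusted p were 0.63 and 0.85, and iscR, the regulator of cluster assembly, was at -0.67 ± 0.45 (adjusted p = 0.26).

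Carbon monoxide binds the haem of terminal oxidases, so the oxidase genes were read as their own comparison. The arrays hold no separate group given the ruthenium compound without its carbon monoxide. Whether the gas or the rest of the compound lies behind a change was therefore not tested. All 5 genes of cytochrome bo oxidase, the main oxidase under high aeration, fell, also adjusted over the list alone and with any experiment left out. cyoA was at -4.11 ± 0.44, cyoB at -4.47 ± 0.58, cyoC at -3.80 ± 1.40, cyoD at -3.67 ± 0.65 and cyoE at -3.38 ± 0.74, or 10.4-fold to 22.1-fold lower. The list had a camera adjusted p of 1.7e-12 and an adjusted p = 0.093 with an estimated correlation. The genes of cytochrome bd-I oxidase, which has a high affinity for oxygen, went the other way. cydA rose 2.50-fold (1.32 ± 0.54, adjusted p = 0.024) and cydB 2.52-fold (1.33 ± 0.50, adjusted p = 0.021).

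The rise of cydA and cydB was less firm than the fall of the cyo genes. The call of cydA ended without experiment 1, 3 or 4 (1.16, 1.41 and 1.18) and that of cydB without experiment 1, 2 or 4 (1.22, 1.37 and 1.19). Of the 6 genes in the bd oxidase list, 2 were called, and 3 with cydD over the list alone. cydD and cydC encode a transporter needed for oxidase assembly and not the oxidase itself. They were at 1.26 ± 0.83 (adjusted p = 0.054) and 0.055 (adjusted p = 0.95). appB and appC, of the second bd oxidase, were at -0.14 and 0.18 (adjusted p = 0.87 and 0.88). The 6 listed genes had a median of 0.72, with a camera adjusted p of 0.021 and an adjusted p = 0.18 with an estimated correlation.

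**Figure D2:**
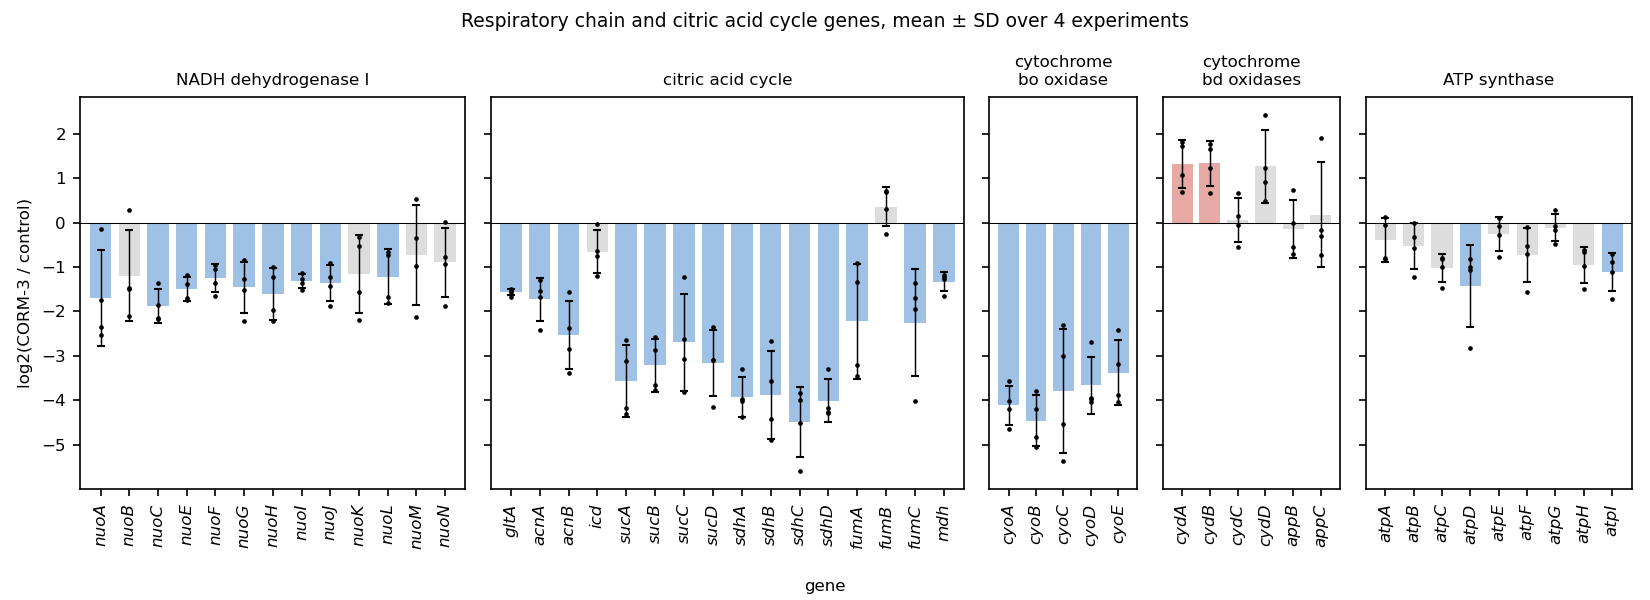
Mean log2 ratio of CORM-3-treated over control RNA for the measured genes of NADH dehydrogenase I, the citric acid cycle, the bo and bd oxidases and ATP synthase (bars, mean ± SD over 4 experiments; points, single experiments). Blue bars mark genes called lower, red bars genes called higher and grey bars genes not called. The 5 cyo genes lie between -4.47 and -3.38 and cydA and cydB at 1.32 and 1.33.

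The citric acid cycle fell as a group, with 14 of 16 genes called lower and 15 over the list alone. The 4 genes of succinate dehydrogenase lay lowest. sdhC was at -4.49 ± 0.79, sdhD at -4.01 ± 0.48, sdhA at -3.92 ± 0.45 and sdhB at -3.89 ± 0.99, or 14.8-fold to 22.5-fold lower. sucB, of the 2-oxoglutarate dehydrogenase complex, was at -3.22 ± 0.59 (adjusted p = 0.00013). gltA, citrate synthase at the entry of the cycle, was at -1.57 (adjusted p = 0.0046). icd was at -0.66 (adjusted p = 0.27), and fumB, the fumarase used without oxygen, at 0.36 (adjusted p = 0.58). The 16 cycle genes had a median of -2.62, with a camera adjusted p of 9.0e-21 and an adjusted p = 0.083 with an estimated correlation, the lowest of all lists in that setting.

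Of 13 genes of NADH dehydrogenase I, the proton-pumping entry to the respiratory chain, 9 fell, and 12 over the list alone. nuoC was at -1.88 ± 0.38, nuoH at -1.61 ± 0.58, nuoE at -1.50 ± 0.28 and nuoI at -1.32 ± 0.16 (adjusted p = 0.0024, 0.0098, 0.0077 and 0.013). The 13 nuo genes had a median of -1.32, with a camera adjusted p of 3.1e-11 and an adjusted p = 0.15 with an estimated correlation. Without experiment 1, 2 or 3 the called nuo genes numbered 3, 2 and 4. Of the 9 ATP synthase genes all had ratios below 0, and 2 were called, atpD (-1.43 ± 0.93) and atpI (-1.11 ± 0.43), against 4 over the list alone. Neither call held with any experiment left out (-1.63 to -0.97 for atpD and -1.25 to -0.91 for atpI). Their list had a median of -0.73, with a camera adjusted p of 0.00060 and an adjusted p = 0.12 with an estimated correlation.

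Genes for the use of glycerol, the carbon source of the cultures, fell too, with 8 of 11 called lower and 9 over the list alone. glpT and glpQ, for uptake and cleavage of glycerol phosphate compounds, were at -2.47 ± 0.87 and -2.09 ± 0.59 (adjusted p = 0.0018 and 0.0021). glpF, the glycerol channel, was at -1.90 ± 0.69 and glpD, the aerobic glycerol 3-phosphate dehydrogenase, at -1.56 ± 0.56. glpR, their repressor, was at 0.24 (adjusted p = 0.72). The 11 glycerol genes had a median of -1.50, with a camera adjusted p of 3.0e-08 and an adjusted p = 0.093 with an estimated correlation. Without experiment 1, 2 or 3 the called genes numbered 3, 4 and 5, and the call of glpD ended without experiment 1 or 2 (-1.38 and -1.44).

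The genes of the general stress response under sigma S lay lower as well, with 7 of 16 called lower. Adjusted over the list alone, 10 were lower and 1 higher. talA, a transaldolase, was at -2.26 ± 1.63, osmE at -1.68 ± 0.65, wrbA at -1.57 ± 0.62 and elaB at -1.57 ± 0.90, with adjusted p from 0.0096 to 0.024. rpoS, which encodes sigma S itself, was at -1.07 (adjusted p = 0.035). otsA, also called lower, was at 0.11 with CORM-3 RNA in Cy3 and at -2.46 with it in Cy5. The list's median was -1.08, with a camera adjusted p of 2.7e-06 and an adjusted p = 0.15 with an estimated correlation. Without experiment 2, 3 or 4 the called genes numbered 2, 0 and 4.

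The 18 heat shock chaperone and protease genes all had ratios above 0, and 4 of them rose, against 13 over the list alone. dnaJ (1.47 ± 0.79), groS (1.46 ± 0.44) and clpB (1.36 ± 0.89) encode chaperones, and rpoH (2.30-fold higher) encodes the heat shock sigma factor. Their adjusted p were 0.025, 0.012, 0.047 and 0.034. ibpA, a small heat shock protein, was at 1.12 ± 0.57 (adjusted p = 0.053). The list's median was 0.85, with a camera adjusted p of 1.1e-08 and an adjusted p = 0.15 with an estimated correlation. The called genes numbered 0 without experiment 1 or 3 and 2 without experiment 4.

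The redox stress lists did not pass the test as groups. Of 12 SoxRS genes, sodA (-1.94 ± 0.56), fumC (-2.25 ± 1.21) and acnA (-1.73 ± 0.49) fell, also over the list alone. All 3 calls ended on the arrays with CORM-3 RNA in Cy5 alone (-1.71, -2.38 and -1.46). fumC and acnA are citric acid cycle enzymes and stand in that list too, and sodA encodes a superoxide dismutase. soxS, the response's activator, was at 0.94 ± 0.98 (adjusted p = 0.21). The list's camera adjusted p was 0.11. limma called none of the 10 OxyR genes, the 9 nitric oxide response genes, the 20 SOS genes and the 9 acid resistance genes, over all genes or over the list alone. At an unadjusted p under 0.05, 2 SOS genes were higher and the other lists had 0. Camera adjusted p were 0.58 for OxyR, 0.58 for nitric oxide, 0.81 for SOS and 0.81 for acid resistance. katG, a catalase, was at -0.50 ± 0.44 (adjusted p = 0.42), norV, a nitric oxide reductase, at 0.37 ± 0.72 (adjusted p = 0.62) and recA at 0.14 ± 0.77 (adjusted p = 0.88).

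**Figure D3:**
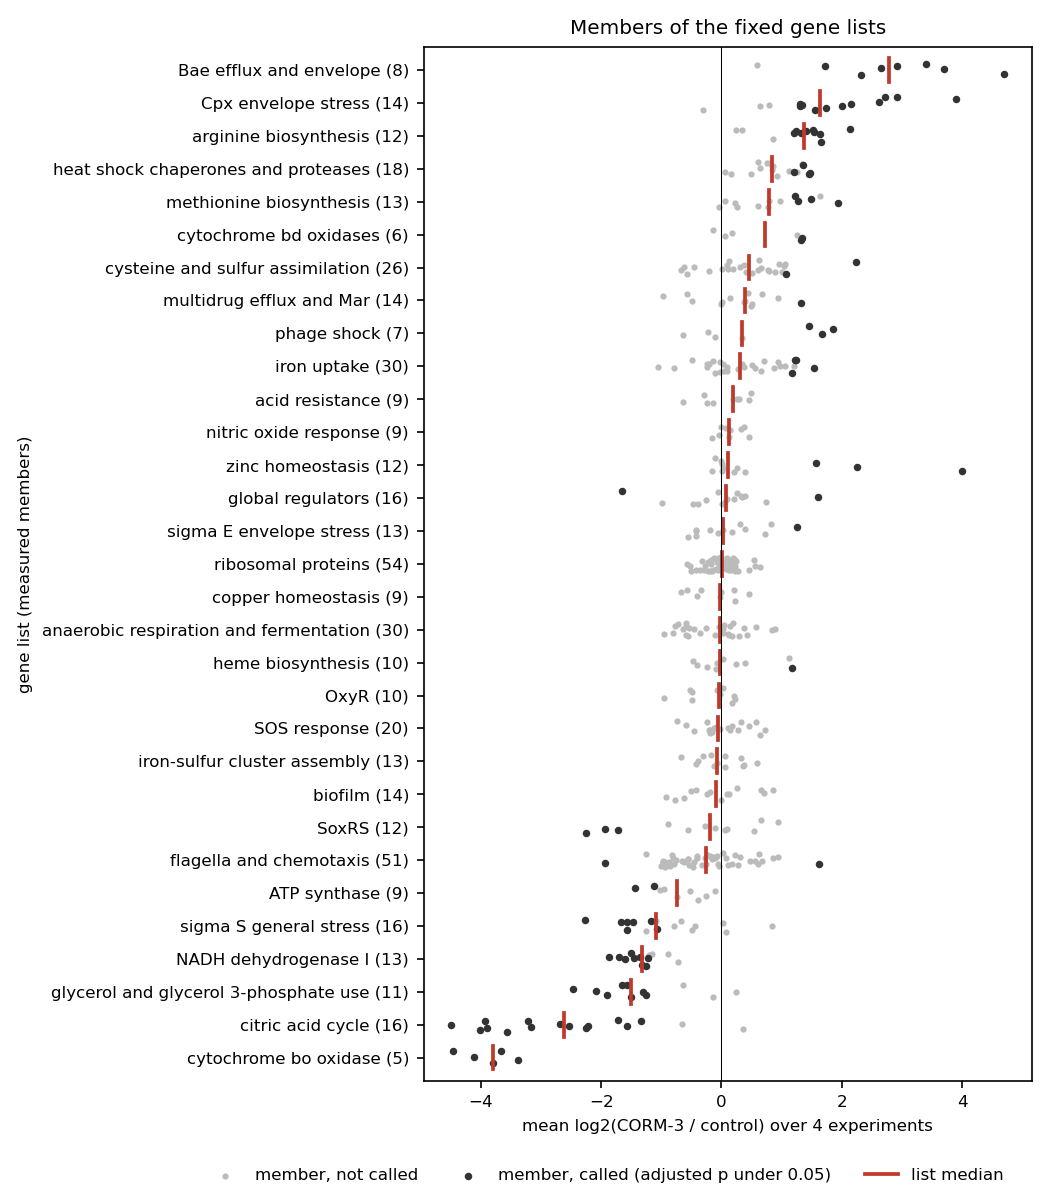
Mean log2 ratio of CORM-3-treated over control RNA, over 4 experiments, of each measured member of the 31 gene lists, with the number of measured members after each list's name. Dark points are members called at an adjusted p under 0.05, grey points are other members and red lines are list medians. Medians run from -3.80 for cytochrome bo oxidase to 2.79 for the Bae list.

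Amino acid biosynthesis genes were among those that rose. Of 12 arginine genes 9 rose, and 10 over the list alone. argA, the first enzyme of the pathway, was at 2.14 ± 0.71, artJ, an arginine-binding transport protein, at 1.66 ± 0.45, argG at 1.64 ± 0.51 and argE at 1.41 ± 0.38 (adjusted p = 0.0025, 0.0058, 0.0076 and 0.012). The list's median was 1.37, with a camera adjusted p of 1.6e-10 and an adjusted p = 0.11 with an estimated correlation. Without experiment 1, 2 or 3 the called genes numbered 5, 4 and 4, and the call of argE ended without experiment 1 or 2 (1.45 and 1.23).

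Of 13 methionine genes 4 rose, and 6 over the list alone. metF, which makes methyltetrahydrofolate, was at 1.94 ± 0.71, metN, of the methionine importer, at 1.49 ± 0.38, metJ, the pathway's repressor, at 1.27 ± 0.25 and metB at 1.22 ± 0.67, with adjusted p from 0.0046 to 0.047. metJ was at 0.33 with CORM-3 RNA in Cy3 and at 2.22 with it in Cy5. Its call ended with any 1 experiment left out (1.19 to 1.35). The list's median was 0.79, with a camera adjusted p of 1.4e-05 and an adjusted p = 0.11 with an estimated correlation. Of 26 cysteine and sulfur genes, sbp, a sulfate-binding protein (2.23 ± 1.40, adjusted p = 0.015), and cbl, a regulator of sulfur starvation genes (1.08 ± 0.36, adjusted p = 0.045), rose, against 6 over the list alone. That list had a median of 0.46, with a camera adjusted p of 0.0020 and an adjusted p = 0.20 with an estimated correlation. The called genes numbered 2, 2 and 1 for methionine without experiment 1, 2 or 3. They numbered 1 for cysteine without experiment 1 and 0 without any other.

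The flagella and chemotaxis list had a median of -0.25 over 51 genes, with a camera adjusted p of 0.014, which ended without experiment 3, and an adjusted p = 0.18 with an estimated correlation. It held 1 gene called lower and 1 called higher, also over the list alone. fliC, the flagellin gene, was at -1.93 ± 0.94 (adjusted p = 0.0096), and cheR, a chemotaxis methyltransferase, at 1.62 ± 0.87 (adjusted p = 0.020). The call of fliC ended without experiment 1 or 3 (-1.74 and -1.59) and that of cheR without experiment 2 or 3 (1.26 and 1.53). The biofilm list had no called gene in limma over all genes or over the list alone, with 3 higher and 3 lower at an unadjusted p under 0.05 and a camera adjusted p of 0.81. bhsA was at 0.85 ± 0.86, tqsA at 0.70 ± 0.55 and bssS at 0.66 ± 0.30 (adjusted p = 0.22, 0.25 and 0.23). The 54 ribosomal protein genes centred on 0.010, with none called by limma over all genes, over the list alone or at an unadjusted p under 0.05 (camera adjusted p = 0.81).

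Among 16 global regulators, arcA (b4401), which represses aerobic metabolism genes when oxygen is short, was 3.15-fold lower (-1.65 ± 0.32, adjusted p = 0.0046). phoB, the phosphate starvation regulator, rose (1.60 ± 0.49, adjusted p = 0.0082). Both calls held over the list alone, and the list's camera adjusted p was 0.81. Each call ended in 1 orientation, that of phoB with CORM-3 RNA in Cy5 (0.90, against 2.31 in Cy3) and that of arcA with it in Cy3 (-1.19, against -2.12 in Cy5). fnr was at 0.25 ± 0.59 (adjusted p = 0.73) and fis at 0.015 ± 0.35 (adjusted p = 0.99). The 30 genes of anaerobic respiration and fermentation held no call by limma, over all genes or over the list alone, with 2 higher and 3 lower at an unadjusted p under 0.05 (camera adjusted p = 0.54). In the multidrug efflux and Mar list tolC, the outer membrane channel of efflux pumps, rose at the edge of the threshold (1.33 ± 0.87, adjusted p = 0.050 after rounding), as the only one of 14 members and also over the list alone (camera adjusted p = 0.21). Of 10 haem synthesis genes hemL rose (1.17 ± 0.38, adjusted p = 0.030), also over the list alone. The haem list's median was -0.024 and its mean 0.17, with a camera adjusted p of 0.63. The call of tolC ended without experiment 1, 2 or 3 (1.51, 1.15 and 1.01), and that of hemL with any experiment left out (1.00 to 1.29).

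With the preset correlation 17 of the 31 lists passed an adjusted p of 0.05 in camera, 10 upward and 7 downward. With a correlation estimated from the 4 experiments no list passed, and 9 were at an unadjusted p under 0.05. In data simulated with the same number of experiments, a list of 12 genes shifted by 1 on the log2 scale gave camera p = 5.8e-12 with the preset correlation and p = 0.0054 with an estimated one. These p are unadjusted, and the simulated noise was independent between genes. The simulation therefore cannot show how either setting serves lists of correlated genes. In the real data the glycerol and ATP synthase lists had estimated correlations of -0.043 and -0.076, below the preset 0.01. Their unadjusted camera p still rose, from 7.8e-09 to 0.0090 and from 0.00021 to 0.031. A correlation above the preset one therefore does not account for the loss of these calls. Other lists had higher estimates, up to 0.47 for NADH dehydrogenase I.

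The dyes themselves were compared through the exchanged arrays. limma called a dye effect for 30 genes, 24 higher in Cy3 and 6 higher in Cy5, and 2 of them, ymgG and feoB, were also among the genes changed by CORM-3. This count was 0 to 3 with 1 experiment left out. Across all genes the mean responses of the 2 orientations correlated at r = 0.22, with genes not being independent replicates. Of the 274 changed genes, 16 had orientations over 2 apart on the log2 scale. Among them spy was at 3.46 with CORM-3 RNA in Cy3 and 5.94 with it in Cy5, while ymgD was at 6.52 and 3.59. In the 274, feoB, yeeP, otsA and pyrE had opposite signs in the orientations. With CORM-3 RNA in Cy5 alone most lists held fewer calls. The called genes numbered 5 for cytochrome bo oxidase, 9 for the citric acid cycle, 5 for Bae, 4 for Cpx, 3 for NADH dehydrogenase I, 2 each for zinc, heat shock, methionine, arginine and glycerol, and 1 for sigma S. They numbered 0 for phage shock, iron uptake, bd oxidases, cysteine, SoxRS and ATP synthase, and the single higher calls of the sigma E, flagella, multidrug efflux, haem and regulator lists ended. With it in Cy3 alone they numbered 12 for the citric acid cycle, 7 each for Cpx and glycerol, and 3 each for NADH dehydrogenase I, arginine and sigma S. They numbered 2 for heat shock and 1 each for methionine, bd oxidases and ATP synthase. The single higher calls of the sigma E, flagella, multidrug efflux and haem lists ended there too, so these losses were not particular to 1 orientation.

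**Figure D4:**
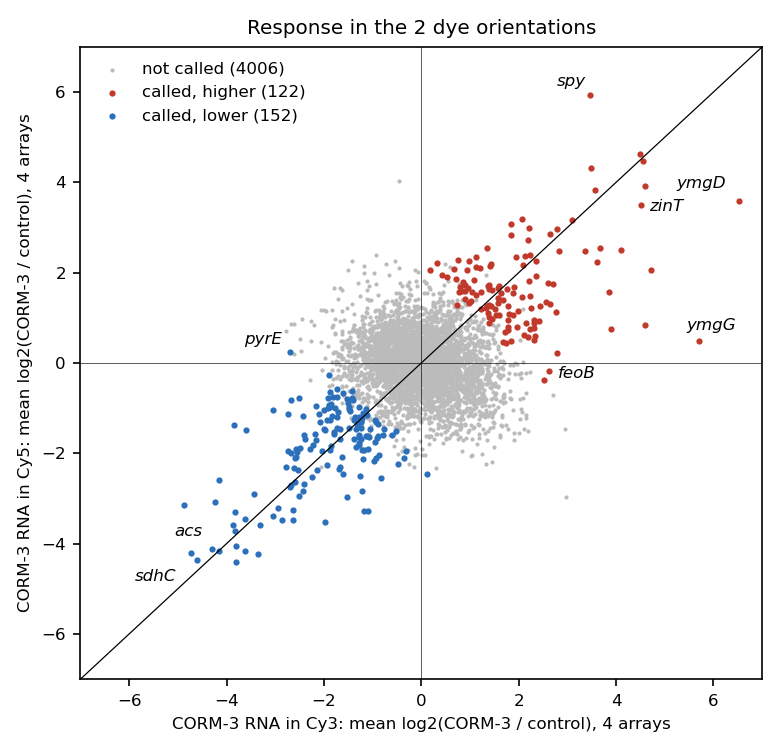
Mean log2 ratio of CORM-3-treated over control RNA on the 4 arrays with CORM-3 RNA in Cy3 (horizontal) against the 4 arrays with it in Cy5 (vertical), 1 point per gene or unnamed probe, with the line of equality. Red points are the 122 genes called higher, blue points the 152 called lower and grey points the 4006 not called. ymgG (5.71 and 0.49) and feoB (2.63 and -0.18) lie far from the line.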

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

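Tests chosen after results were seen are those of adjacent spots and of falls read in the other orientation, which replaced earlier forms of both, and of orientation differences repeated in experiments 3 and 4. Single experiments that stood apart were sought with Dixon's test among the 4 values of each of 142 named genes, where chance marks about 1 gene in 20, and 6 genes were marked. entB was at 0.55 in experiment 1 and between 1.32 and 1.44 in the others. rplI was at -0.37 in experiment 2 against 0.85 to 1.08, and atpD at -2.81 in experiment 3 against -1.07 to -0.82. glpF was at -2.92 in experiment 4 against -1.69 to -1.49. In experiment 1 cyoD was at -2.70 against -4.05 to -3.95, and sdhD at -3.29 against -4.29 to -4.18.

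The response of 2 named genes differed between the dye orientations in limma's test of that difference. ymgG was 5.21 higher with CORM-3 RNA in Cy3 than in Cy5 (5.71 against 0.49, adjusted p = 0.031), and feoB was 2.82 higher (2.63 against -0.18, adjusted p = 0.044). Strong compression of all ratios in one orientation is argued against as the source of such gaps, since the Cy5 responses were nearly as wide as the Cy3 ones. Their SD over the 274 changed genes was 0.910 times that of the Cy3 responses (reduced major axis slope, 95% interval 0.853 to 0.969). This interval lies below 1, so a slight compression stays possible. A dye bias of single probes may account for the gaps. Of 23 changed genes whose orientations lay over 2 apart in experiments 1 and 2, 82.6% (19 genes, exact interval 61.2% to 95.0%, exact binomial p = 0.0026, two-sided) differed the same way in experiments 3 and 4. The binomial test and both intervals here treat genes as independent and leave out the spread between experiments, so they overstate the certainty. No biological explanation was tested, and such a dye bias cancels in the mean of both orientations only if it is additive on the log scale.

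The fall of 152 genes, with respiratory and citric acid cycle genes at its head, was weighed against 2 technical sources. A local fault of the slides would also lower neighbouring spots, but the 540 spots next to spots of fallen genes, of which 24 were called themselves, had a median ratio of -0.014 (95% interval -0.078 to 0.040). A dye bias turns its sign between the orientations, so it was read on arrays that had no part in choosing the genes. The 144 genes called lower on the arrays with CORM-3 RNA in Cy3 alone had a median of -1.07 on the other arrays (95% interval -1.42 to -0.79), and the 58 chosen the other way round had -2.41 (95% interval -2.68 to -1.87). Both argue against these sources for the falls as a set. The intervals treat genes or spots as independent and leave out the spread between experiments, so they are too narrow. Of the 144 genes, 33 lay above 0 on the other arrays, but only 92 of the 144 were among the 152 falls. Of these 152, 150 lay below 0 in both orientations, which their choice by the mean of both favours. Single genes stay open to a dye bias.

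Turning the sign of whole experiments gives 8 distinct patterns, too few for a share under 0.05. The real pattern gave 274 changed genes and was the only 1 with as many, and the highest of the others gave 0.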

How the results depend on the processing

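All tests here were planned. On 8 arrays as independent values, with no replicate block, 284 genes were called, 245 of them among the 274, and with the experiment as a replicate block 351 (264 shared), or 326 with a dye term (260 shared). The correlation within a block was estimated at -0.14 without the dye term and at 0.055 with it. A negative value narrows the standard error of the mean, so the count of 351 is not a firmer one. The other settings with all experiments gave 270 to 292 genes, except the arrays with CORM-3 RNA in Cy5 alone. These gave 102 genes (92 shared), 44 higher and 58 lower, against 276 (169 shared) on the arrays with it in Cy3, and the cause was not tested. With 1 experiment left out, which leaves fewer samples, the counts ran from 151 to 214 in all, 71 to 89 higher and 78 to 125 lower. Experiments 1, 2 and 3 each moved the count by over 1.5 times (162, 153 and 151). The number of called genes in the 2 oxidase lists, 7 in the main test, ran from 5 to 8 over the settings, but it pools falls and rises. With an experiment left out or 1 orientation alone, all 5 bo calls held. The 2 bd calls went to 0 without experiment 1 or 4 and on the arrays with CORM-3 RNA in Cy5. With an estimated correlation 0 of 31 lists passed, against 17 with the preset one. The lists were also run with centring, equal spread, complete genes, 8 arrays without a block and each experiment left out. There phage shock (without experiment 2 or 3) and flagella (without experiment 3) lost their calls and the other calls held. The dye effect fell from 30 genes to between 0 and 3 with 1 experiment left out. Of the 78 called named genes, feoB turned its sign, to -0.18 on the arrays with CORM-3 RNA in Cy5. Over all 274 changed genes 3 turned there and 1 on the arrays with it in Cy3. Over all alternatives the values of the 78 called named genes kept direction and call 1245 times and direction alone 158 times. Of these losses 19 were on the Cy3 and 38 on the Cy5 arrays alone, and 25, 22, 26 and 16 without experiment 1, 2, 3 and 4. The pairing by experiment ended 1 of their calls as a block and none with a dye term. Of the 64 other named genes 7 gained a call with the block and 5 with the dye term. Over all alternatives their values gained a call 33 times and changed sign without a call 27 times. Centring, equal spread and quantile normalisation ended no call of the 78 called named genes, and kept 267, 270 and 273 of the 274 calls. They put the median of all genes between -0.0044 and 0.012 against -0.0028. Signal over background was not used here, so its limit is not known.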

Other observations

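The tests of the ArcA and CRP gene lists were fixed before their results were seen. The 10 gene groups in the next 3 paragraphs were chosen after the values were seen, so their tests describe these data and are not independent evidence. Each camera adjusted p there is over these 10 groups with the preset correlation, and with an estimated correlation none of the 10 passed (lowest adjusted p = 0.074, with 4 at an unadjusted p under 0.05).

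Genes of acetate and glyoxylate use fell beside acs, with 8 of 9 measured called lower (median -1.28, camera adjusted p = 6.9e-11, and adjusted p = 0.079 with an estimated correlation). yjcH and actP, which lie next to acs and include the acetate transporter, were at -3.54 ± 1.21 and -3.44 ± 0.89, and glcB, a malate synthase, at -2.54 ± 0.54. The aerobic formate dehydrogenase genes fdoG, fdoH and fdoI fell to -3.17 ± 0.49, -2.94 ± 0.48 and -2.72 ± 0.91, and fdhE was at 0.17 (adjusted p = 0.88). All 3 genes of the galactose transporter fell, led by mglB at -3.05 ± 0.43. Of 5 genes for degradation of gamma-aminobutyrate and lysine 3 fell, led by lhgD at -2.73 ± 1.17. The camera adjusted p of these 3 groups were 2.0e-05, 4.0e-07 and 2.5e-05, against adjusted p = 0.11, 0.10 and 0.13 with an estimated correlation.

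Of 6 genes repressed by Zur, the zinc-sensing repressor, 5 rose (camera adjusted p = 4.4e-08, and adjusted p = 0.074 with an estimated correlation). Besides zinT, ykgM, znuA and znuC this was pliG (2.19 ± 0.40), while znuB was at -0.16 (adjusted p = 0.86). The group shares 4 of its 6 genes with the zinc list. In the phosphate starvation regulon 6 of 16 genes rose, 1 was lower over the list alone and 8 lay below 0. Those that rose were pstS (2.60 ± 0.35), pstB (2.34 ± 0.96), pstC (1.82 ± 0.78), phoU (1.73 ± 0.75), phoB (1.60 ± 0.49) and pstA (1.29 ± 0.44). phoA, the alkaline phosphatase gene of the same regulon, was at 0.54 (adjusted p = 0.46) and phoR at -0.10 (adjusted p = 0.92). phoH was at -2.19 ± 2.03 (adjusted p = 0.060), and ugpA, ugpE, ugpQ, ugpC and ugpB, for glycerol phosphate uptake and cleavage, lay between -0.89 and -0.46. As a group it had a median of -0.030, a mean of 0.39 and a camera adjusted p of 0.057.

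In amino acid pathways, aroF (2.88 ± 0.26) and tyrA (2.31 ± 0.87) rose and aroG (-1.36 ± 0.61) fell among 8 genes of aromatic synthesis and transport (camera adjusted p = 0.026, and adjusted p = 0.13 with an estimated correlation). Of 7 histidine genes 3 rose, led by hisC at 1.63 ± 0.35, and all 7 did so adjusted over the list alone (camera adjusted p = 2.3e-06, and adjusted p = 0.074 with an estimated correlation). Of 11 branched-chain genes 3 fell, led by ilvC at -2.03 ± 0.41 (camera adjusted p = 0.040, and adjusted p = 0.19 with an estimated correlation). Of 8 outer membrane protein genes ompC and ompX (1.95 ± 0.59) rose while ompW (-1.43 ± 0.94) and lamB (-1.39 ± 0.64) fell. ompF was at -0.12 ± 0.16 (adjusted p = 0.87), and the group's camera adjusted p was 0.60.

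A hypothesis for the fall of respiratory and carbon-oxidation genes is repression by ArcA, which acts when the respiratory chain is held back. Its test used 22 measured ArcA-repressed genes outside the 31 lists, whose median was -1.11 (95% interval -1.17 to -0.83), with 10 called lower (camera p = 5.0e-10, and p = 0.021 with an estimated correlation). Lower activity of CRP with cyclic AMP is a further candidate explanation. Its 45 measured sugar and nucleoside genes had a median of -0.55 (95% interval -0.74 to -0.33), with 8 called lower (camera p = 3.1e-08, and p = 0.0086 with an estimated correlation). The 2 intervals treat genes as independent and leave out the spread between experiments. Both explanations stay open, since many of the fallen genes are known targets of both regulators and no regulator mutant was analysed here. Besides, 5 of the 22 ArcA genes also stand in the acetate group, and arcA itself was at -1.65.

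Called genes lay next to each other on the chromosome. Of 266 called named genes, 112 (42.1%) had an adjacent measured gene called in the same direction, against a mean of 17.4 and a highest value of 39 in 10000 random gene orders (permutation p = 0.0001, the smallest they can give). Ratios of adjacent genes correlated at r = 0.36 over 4030 pairs, and ratios of adjacent spots on the slide at r = 0.041 over 7990 pairs, with genes and spots not being independent replicates.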
